A study of Mus musculus with 6 samples.

How the data were processed

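RNA from 6 mouse uterus samples, 3 of the DI group and 3 of the PBS group, was selected for poly(A), made into stranded libraries by the dUTP method and read as paired ends, per the labels. The submitters' processing notes name cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2, edgeR and the build mm10, without the role of each, and the annotation is not given in the sources used here. Of 32825 genes shared with the GENCODE annotation of that build, 32824 lie on the same chromosome but 640 (1.95%) have the same start and end, so genes are placed by chromosome only.

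The deposited table gives FPKM, fragments scaled to gene length and library size, for each gene and sample. It also gives whole-number counts, and these deposited values are taken to be expected counts, an estimate rather than a tally of reads, because 1165 to 1267 genes per library have a count of 4, against 642 to 699 with 3 and 378 to 437 with 5. A count of 8 is also in excess (433 to 520 genes, against 357 to 403 with 7 and 253 to 295 with 9). Whether 1 read pair stands for several counts is not known. The table holds 34819 genes, of which 1466 have no symbol and 1079 are 0 in all libraries, and annotation cells had been removed in 4250 of its lines. Totals were 53227000 to 63040000 per library, so that 3 counts, the upper limit that a count of 0 allows, are 0.0476 to 0.0564 CPM. Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. They are too low if 1 read pair stands for several counts.

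Counts were filtered with filterByExpr (minimum count 10), scaled with TMM factors (0.946 to 1.07) and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment over 21215 genes. DESeq2 1.42.0 was run on the counts, and limma 3.58.1 with a trended prior on log2(FPKM + 1) over 14457 genes with a mean FPKM of at least 1. The SE of a log2 fold change is its size divided by the square root of the quasi-likelihood F. Log2 CPM used a prior count of 2. The comparison, the gene lists and the rule for named genes were fixed before the data were examined. Cxcl14 was also tested by exact permutation over 20 assignments. Of 33 gene lists, the 32 with at least 5 measured genes were tested with camera at a preset correlation of 0.01 on the count object of the edgeR fit, adjusted over lists, and their members were also adjusted over the list alone. Camera had first been run on log2 CPM while the data were explored, and the count object was taken afterwards because the planned test names the matrix of the all-gene fit; on log2 CPM 20 lists were lower and 1 was higher. The test fry asks whether a list's genes move on balance one way, which passed for 3 lists (MHC class II, macrophage and complement, all lower), or in either direction, which passed for 19. Terms with 10 to 300 tested genes (2334 GO, 315 KEGG) were tested with camera in the same way.

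The genes named are Cxcl14, then 10 higher and 10 lower genes, and up to 4 members of each list with the smallest unadjusted p, with further list members, chosen after their values were seen, as values. The 10 in each direction are those with the largest change among genes past the threshold without overlap between groups, filled with the smallest unadjusted p among genes without overlap. As edgeR called 0 genes at an adjusted p below 0.05 (3105 at an unadjusted p, 1123 by DESeq2 and 1 by limma), all 20 are filled places. Predicted models and immunoglobulin or T-cell receptor segments were skipped there. Not every list member that this rule selects is reported.

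The tools were tested on simulated data, 3 sets drawn from the means, library sizes and dispersions of the measured genes with 200 genes changed, for the DI against PBS comparison. edgeR recovered 10.0% of genes changed 2-fold and 44.7% of those changed 4-fold over 20618 genes, with 3.67 false calls per set. DESeq2 recovered 38.3% and 70.0% over 21178 genes with 84.0 false calls. For limma, run here on log2(CPM + 1) in place of FPKM, these were 13.7% and 46.7% over 16329 genes with 4 false calls. Of 600 random lists, 1.5% had a camera p below 0.05, and a list of genes shifted 2-fold had p of at most 7.44e-24 with the preset and 0.000460 with the estimated correlation. Simulated genes were drawn independently of each other, so these lists cannot show how the preset performs on correlated genes. In the measured lists the estimated correlation reached 0.926 (interferon-stimulated genes). The alternatives set beforehand were scaling, filters, pseudocount, trend, weights, a replicate block, each library left out, DESeq2 and the estimated correlation. Alternatives chosen after seeing the data were counts divided by 4, no TMM factors, a robust fit, DESeq2 with a block or without each library, camera on log2 CPM, lists without Reg3b and Reg3g (and Lypd8) or without H2 genes, and list members and medians without each library.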

Results

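Polyadenylated RNA was sequenced from 6 samples of mouse uterus in 2 groups. The 3 samples of the DI group came from mice given dimethyl itaconate, an ester of the immune metabolite itaconate, by mouth at 400 mg/kg daily for 7 days. The 3 samples of the PBS group came from mice given phosphate-buffered saline daily for the same time. The series title concerns endometritis, an inflammation of the uterine lining, caused by Escherichia coli, but the labels do not state whether these uteri had been infected, nor that the samples of a group came from separate animals. Total estimated counts were 61791000, 62399000 and 60454000 in the DI libraries and 55382000, 63040000 and 53227000 in the PBS libraries. Levels below are counts scaled to library size (CPM), given as mean ± SD in DI against PBS with n = 3 per group, and changes are log2 fold changes of DI minus PBS ± SE.

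The first comparison asked whether the transcript of CXCL14, the chemokine named in the series title, differed between the groups. Cxcl14 (ENSMUSG00000021508, chromosome 13) stood at 326 ± 21.4 against 156 ± 63.0 CPM, and each DI library lay above each PBS library. Its log2 fold change was 1.06 ± 0.31. The authors' FPKM values averaged 165 ± 7.62 in DI and 72.8 ± 30.7 in PBS. The difference did not pass edgeR's test over all genes (adjusted p = 0.247) and passed that of DESeq2 (adjusted p = 0.0271). The exact two-sided permutation test of log2(FPKM + 1) gave p = 0.1, the smallest value that 3 samples against 3 allow. By edgeR's p Cxcl14 ranked 1164 among 21215 tested genes, and 22.2% of these had no overlap between the groups. Its lowest library was PBS 3 (84.2 CPM), without which the log2 fold change was 0.77.

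**Figure D1:**
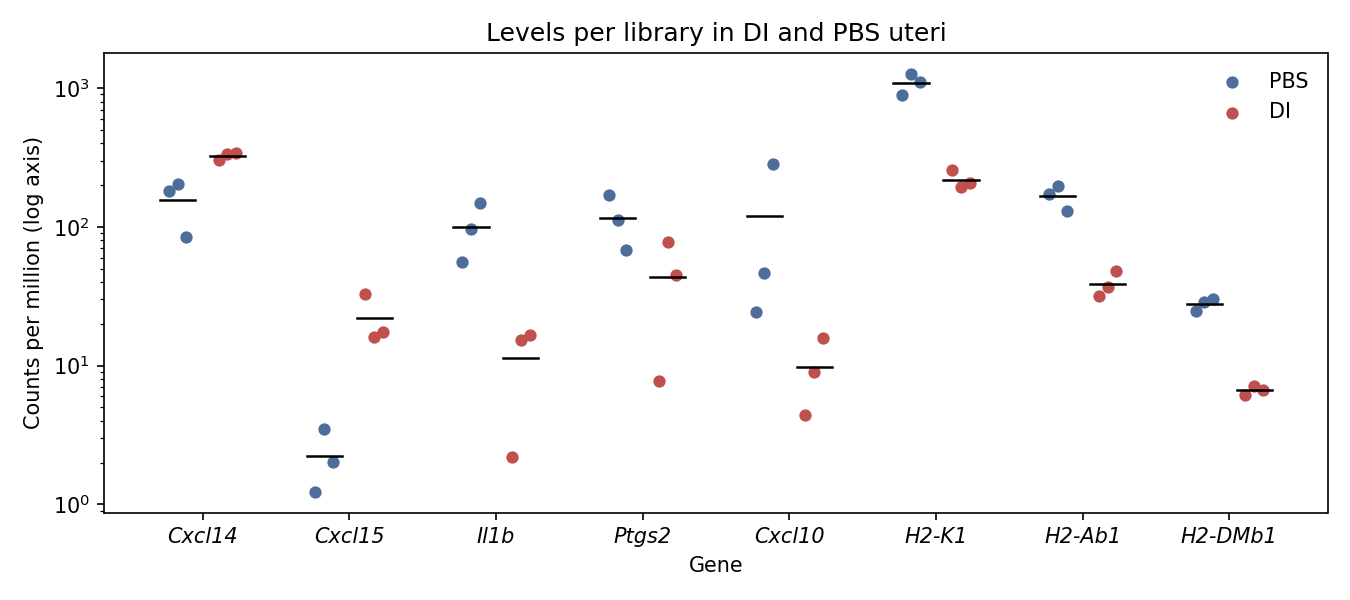
CPM (log axis) of 8 genes in each library, with PBS in blue, DI in red and a black bar at each group's mean. Cxcl14 and Cxcl15 were higher in each DI library than in each PBS library, and H2-K1 (219 ± 34.5 against 1088 ± 192 CPM), H2-Ab1, H2-DMb1, Il1b and Cxcl10 were lower in each DI library, while Ptgs2 overlapped between the groups.

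Across all genes, the question was which transcripts differed between DI and PBS uteri. The libraries did not all sort by group. On log2 CPM, DI 2 correlated at 0.965 with PBS 1, 0.964 with PBS 2 and 0.948 with PBS 3. Its correlation was 0.958 with DI 1 and 0.956 with DI 3. The lower genes with the smallest unadjusted p included 3 of antigen presentation. These, and the ribosomal protein gene Rps18 given below, lie on chromosome 17. H2-DMb1 (ENSMUSG00000079547, chromosome 17), part of the chaperone that loads peptides onto MHC class II molecules, stood at 6.65 ± 0.504 against 27.9 ± 2.80 CPM (-2.07 ± 0.14). H2-K1, an MHC class I heavy chain, stood at 219 ± 34.5 against 1088 ± 192 CPM (-2.31 ± 0.19), and H2-Ab1, an MHC class II chain, at 38.9 ± 8.50 against 166 ± 34.0 CPM (-2.10 ± 0.22). H2-Ea, a gene whose expression differs between mouse strains, ranged from 1.65 to 32.1 CPM inside DI and from 0.118 to 74.1 CPM inside PBS, and the labels do not name the strain. On the higher side, the chemokine Cxcl15 stood at 22.1 ± 9.40 against 2.24 ± 1.13 CPM (3.30 ± 0.48).

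Other genes with the smallest unadjusted p among those whose groups did not overlap were the interleukin 10 receptor chain Il10ra (-1.26 ± 0.13), the hexokinase Hk2 (-1.17 ± 0.15), Ldhd (-1.14 ± 0.11), Plbd1 (-1.26 ± 0.11), Slc37a2 (-1.60 ± 0.14) and the lipid transporter Mfsd2a (-1.24 ± 0.15) on the lower side. On the higher side they were the organic cation transporter Slc22a3 (1.05 ± 0.13), the transcription regulators Id4 (1.21 ± 0.17) and Ebf4 (1.08 ± 0.16), Tspan18 (0.98 ± 0.14), Cachd1 (0.61 ± 0.09), Tln2 (0.86 ± 0.13), Pcdh18 (0.66 ± 0.11), Synpr (2.71 ± 0.45) and Nptx1 (1.81 ± 0.30). The ribosomal protein gene Rps18 stood at 41.0 ± 6.59 against 281 ± 81.9 CPM, but the pseudogenes Rps18-ps3, Rps18-ps5 and Rps18-ps6 had the opposite order, and the sum of Rps18 and its annotated pseudogenes was 489 ± 92.0 against 467 ± 58.5 CPM. The genes of this and the preceding paragraph did not pass edgeR's test over all genes. In DESeq2 the 10 higher and 10 lower genes chosen by rule passed, with adjusted p from 5.80e-28 (H2-DMb1) to 0.00118 (Pcdh18). They had been chosen from the same counts by edgeR's p and lack of overlap, so this is no independent support. edgeR called 0 of 21215 genes, with a smallest adjusted p of 0.0780 for H2-DMb1. At an unadjusted p below 0.05 it gave 1357 higher and 1748 lower genes, where chance gives 1061 in all. DESeq2 called 356 higher and 767 lower genes, and limma on log2(FPKM + 1) called 0 higher genes and 1 lower gene, H2-DMb1 (adjusted p = 0.0194). In simulated data with known changes DESeq2 made 84.0 false calls per set and edgeR 3.67. The groups did not overlap for 4707 genes (22.2%, where chance gives 10%). The balance of directions depended on scaling: with TMM factors 56.3% of the unadjusted edgeR calls were lower, and without them 33.9%, the median of all genes moving from 0.01 to 0.12.

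**Figure D2:**
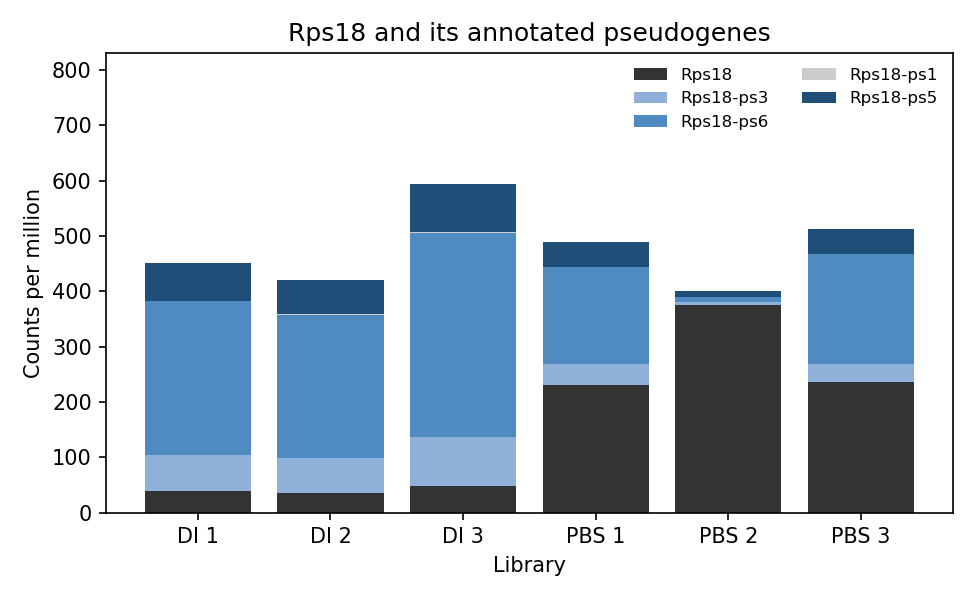
CPM of Rps18 (black) and of its 4 annotated pseudogenes (blue and grey), stacked for each of the 6 libraries. Rps18 itself stood at 41.0 ± 6.59 against 281 ± 81.9 CPM in DI against PBS, and the whole bars at 489 ± 92.0 against 467 ± 58.5 CPM.

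Gene lists written before the data were examined asked which functions moved together, and the proinflammatory mediators had the lowest median of the 32 lists in DI. All 23 measured proinflammatory mediators had a log2 fold change below 0, with a median of -2.63, and 19 of them fell when adjusted over the list alone, against 0 over all genes. Here and below, calls of list members over the list alone or over all genes are edgeR's unless another tool is named. DESeq2 called 17 of the mediators lower over all genes. Cxcl2, which attracts neutrophils, stood at 2.23 ± 1.2 against 35.6 ± 18 CPM (-4.0 ± 0.61), the cytokine genes Il1b and Tnf had log2 fold changes of -3.14 ± 0.77 and -2.91 ± 0.69, and Tnfaip3, a brake on NF-kB signalling, of -2.0 ± 0.37. Il6 (-2.74 ± 1.22) and Ptgs2 (-1.42 ± 0.77) did not pass. With each library left out in turn, 12 of the 19 calls held in all 6 fits. Leaving out PBS 3 gave a list median of -1.75 and log2 fold changes of -2.11 for Tnf and -1.86 for Il6. Leaving out DI 2 gave -2.13 for Ptgs2. As a set the list was lower (camera with a preset correlation, adjusted p = 8.47e-23), and adjusted p = 0.190 with an estimated correlation. Of 23 other chemokines, 9 fell and 1, Cxcl15, rose adjusted over the list alone, against 0 over all genes. Among them were Ccl9 (-2.33 ± 0.32), Cxcl16 (-1.10 ± 0.24) and the interferon-inducible Cxcl10 (-3.60 ± 1.05), and the set was lower (adjusted p = 9.75e-07, and adjusted p = 0.251 with an estimated correlation). Of these 10 calls 3 held in all 6 fits with a library left out. Cxcl10 stood at 24.3 CPM in PBS 1, 46.7 in PBS 2 and 286 in PBS 3. Without PBS 3 its log2 fold change was -1.85 and its call was lost (adjusted p over the list alone = 0.0545).

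Receptors and adaptors that sense bacteria were also lower. Of 21 genes 12 fell adjusted over the list alone and 0 over all genes, among them the lipopolysaccharide co-receptor Cd14 (-1.74 ± 0.31), the inflammasome sensor Nlrp3 (-2.69 ± 0.50) and the lipopeptide receptor Tlr2 (-1.36 ± 0.26). 3 of these calls held in all 6 fits with a library left out. The set had a median of -0.63 (adjusted p = 8.21e-12, and adjusted p = 0.211 with an estimated correlation). Secreted antimicrobial proteins and mucins had a median of -1.49 (adjusted p = 4.15e-08, and adjusted p = 0.190 with an estimated correlation), but in edgeR 0 of 16 passed singly, adjusted over the list alone or over all genes. DESeq2 called 5 of them lower over all genes, among them Pigr (adjusted p = 0.00132) and Slpi (0.0313). Pigr, which carries immunoglobulin A across epithelia, stood at 300.1 ± 135 against 844 ± 119.5 CPM (-1.49 ± 0.34) and the protease inhibitor Slpi had a log2 fold change of -1.42 ± 0.46. That list holds Reg3b, Reg3g and Lypd8, which intestine also makes, and intestinal markers differed between libraries, with a median of 3.14 CPM in PBS 3, 0.110 CPM in PBS 1 and 0.975 to 1.88 CPM in the other libraries. Without PBS 3 these genes turned direction (log2 fold change 0.83 for Reg3b, 0.75 for Reg3g and 0.72 for Lypd8). Without these 3, removed after their values were seen, the median of the other 13 genes was -1.49 (adjusted p = 2.31e-09). Complement genes had a median of -0.95 (adjusted p = 9.80e-07, and adjusted p = 0.0675 with an estimated correlation). That estimate was 0.000562, below the preset of 0.01, so a higher correlation within the list did not cause this loss. The estimate for MHC class II genes was -0.0206, and their adjusted p went from 1.47e-13 to 0.0423, a call that was kept. The preset and estimated settings therefore differ in more than the correlation itself. A loss with an estimated correlation need not mean that members were correlated. Of the 15 complement genes 0 passed in edgeR, adjusted over the list alone or over all genes, with C5ar1, the receptor of the fragment C5a, at -1.54 ± 0.34 and C2 at -0.96 ± 0.26. DESeq2 called 4 lower over all genes, among them C5ar1 (adjusted p = 0.00118) and C2 (0.0255).

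Interferon-stimulated genes and both arms of antigen presentation were lower in DI. All 24 interferon-stimulated genes lay below 0 (median -1.77) and in edgeR 22 fell adjusted over the list alone, against 0 over all genes. DESeq2 called 16 lower over all genes. Usp18 (-1.46 ± 0.35), Ifi27l2a (-1.79 ± 0.44), Rsad2 (-2.25 ± 0.57) and Oas1a (-1.37 ± 0.36) had the smallest p. With each library left out in turn, 0 of the 22 calls held in all 6 fits. Without PBS 3 the list median was -0.93, with Rsad2 at -1.66 and Ifi27l2a at -1.19, and Ifit3, chosen after its values were seen, went from -2.50 ± 0.86 to -1.05. The set gave adjusted p = 3.63e-17, and adjusted p = 0.271 with an estimated correlation. Of 14 MHC class I genes 13 fell in edgeR adjusted over the list alone and 0 over all genes, including the light chain B2m (705 ± 142 against 1663 ± 356 CPM, -1.24 ± 0.22) and H2-Q6 (-1.74 ± 0.29), and 8 of the calls held in all 6 fits with a library left out. DESeq2 called 13 lower over all genes. The set gave adjusted p = 1.90e-20, and adjusted p = 0.190 with an estimated correlation. Its 7 members not named H2 had a median of -1.24 (camera with a preset correlation, adjusted p = 2.01e-07). They were taken by name and not by position, so this does not set aside the neighbourhood of the H2 genes on chromosome 17. Of 10 MHC class II genes 7 fell in edgeR adjusted over the list alone and 0 over all genes, including the invariant chain Cd74 (-1.03 ± 0.16) and H2-DMa (-1.29 ± 0.21), and 7 of the calls held in all 6 fits with a library left out. Over all genes DESeq2 called 7 lower, and limma called H2-DMb1 lower. Leaving out libraries cannot set aside strain variants of the polymorphic H2 genes, which stay open. Cd74 and Ciita (log2 fold change -1.34), which are not named H2, were among edgeR's calls over the list alone. The set gave adjusted p = 1.47e-13. Of the 32 lists, this was the one whose call held with an estimated correlation on the count object (adjusted p = 0.0423 with an estimated correlation), but it did not hold on log2 CPM, on which camera was run first (adjusted p = 0.152 with an estimated correlation).

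**Figure D3:**
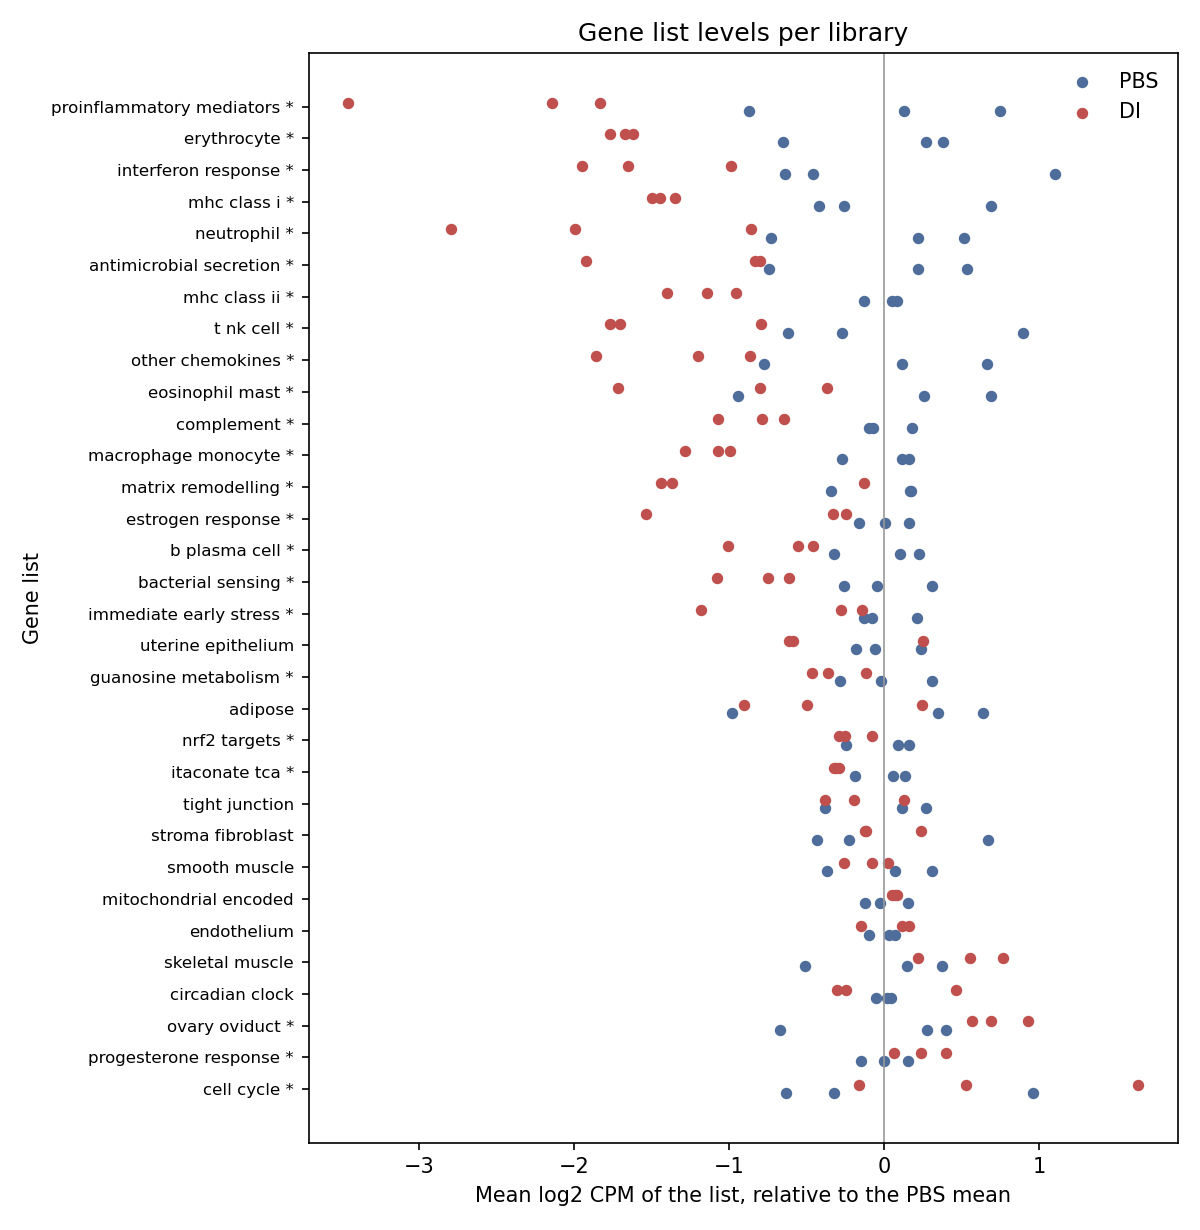
Level of each tested gene list in each library, as the mean log2 CPM of its members relative to the PBS mean, with PBS in blue and DI in red, and an asterisk where the set's adjusted p was below 0.05 with a preset correlation. Proinflammatory mediators lay between -3.46 and -1.83 in DI and between -0.87 and 0.75 in PBS.

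Marker transcripts of leukocytes were lower in DI, read here as transcript levels in whole tissue and not as cell numbers. Of 16 macrophage and monocyte markers 10 fell adjusted over the list alone and 0 over all genes, including Adgre1 (63.2 ± 10.2 against 207 ± 94.0 CPM, -1.71 ± 0.37), Lyz2 (-1.65 ± 0.35) and the growth factor receptor Csf1r (-0.99 ± 0.22). Of these calls 5 held in all 6 fits with a library left out, and the set gave adjusted p = 1.48e-12, and adjusted p = 0.0675 with an estimated correlation. Of 13 neutrophil markers 3 fell adjusted over the list alone and 0 over all genes, Il1r2 (-2.55 ± 0.39), Trem1 (-3.06 ± 0.67) and Clec4d (-2.86 ± 0.71). Of these calls 1 held in all 6 fits, the list median went from -1.52 to -2.68 without DI 2, and the set gave adjusted p = 8.81e-09, and adjusted p = 0.255 with an estimated correlation. Of 17 T and NK cell markers 1, the granzyme gene Gzma (-3.93 ± 0.61, and -3.17 without PBS 3), fell adjusted over the list alone and 0 over all genes. The list median went from -1.19 to -1.80 without DI 3, and the set gave adjusted p = 4.70e-08, and adjusted p = 0.315 with an estimated correlation. Of 12 B and plasma cell markers 3 fell adjusted over the list alone and 0 over all genes, including Ms4a1 (-1.71 ± 0.39) and Ighm (-0.74 ± 0.21), calls that were lost whichever library was left out, with adjusted p = 0.000834 for the set, and adjusted p = 0.315 with an estimated correlation. That set call held under 16 of 24 alternatives (adjusted p 3.07e-05 to 0.556) and was lost among others at a mean FPKM of at least 1 or 5. Eosinophil and mast cell markers had 0 of 12 pass singly in edgeR, with the mast cell tryptase Tpsb2 at -2.23 ± 0.71, while DESeq2 called 2 lower over all genes. Their set gave adjusted p = 0.00445, and adjusted p = 0.372 with an estimated correlation. Without DI 1 or PBS 2 the adjusted p with the preset correlation was 0.0597 or 0.0621. Without DI 1 the list median went from -1.05 to -0.42. All 5 globin and erythrocyte genes fell adjusted over the list alone and 0 over all genes, with Hbb-bs at 4.56 ± 0.475 against 16.2 ± 6.24 CPM. Of these calls 3 held in all 6 fits, and the set gave adjusted p = 3.07e-07, and adjusted p = 0.190 with an estimated correlation.

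Marker lists of the structural cells of the uterus did not pass as sets in the main fit. The adjusted p was 0.0768 for epithelium (median -0.42, Epcam -0.72 ± 0.21), 0.683 for stroma (Wt1 0.47 ± 0.15), 0.683 for smooth muscle (Des -0.96 ± 0.32) and 0.683 for endothelium (Tek 0.25 ± 0.09). Epithelium was lower past the threshold under 8 of 24 alternatives (adjusted p 0.000253 to 0.631), among them no filter on counts, no composition scaling and 4 limma settings on FPKM. The stromal median was -0.08 while its set test pointed up. Leaving out 1 library brought epithelium lower (adjusted p = 0.000253 without DI 3 and 0.00821 without PBS 3), smooth muscle lower (0.0443 without PBS 1) and stroma higher (0.00240 without PBS 3) past the threshold. Among neighbouring tissues, adipose markers did not pass as a set (adjusted p = 0.216, but 0.0158 without DI 3 and 0.0278 without PBS 1, and past it too in limma with no filter on FPKM, all lower), while Fabp4, a fatty acid carrier also made by endothelium and macrophages, fell adjusted over the list alone (-2.49 ± 0.42). Skeletal muscle markers did not pass as a set (adjusted p = 0.147), and their 1 member that rose adjusted over the list alone, Myh1, was at 0.360 CPM in DI and 0 in PBS, a call held in 5 of 6 fits with a library left out. Ovary and oviduct markers were higher as a set (adjusted p = 0.0314, and adjusted p = 0.271 with an estimated correlation), and 1 of 7, the oviduct glycoprotein gene Ovgp1 (17.2 ± 6.22 against 4.23 ± 2.86 CPM; log2 fold change 2.02 ± 0.52, and 2.73 without PBS 1), rose adjusted over the list alone, which held in 1 of 6 fits with a library left out. That set call was lost without DI 1 (0.0790), DI 2 (0.147), DI 3 (0.604) or PBS 3 (0.279), and held under 8 of 22 alternatives.

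Uterine genes known to rise with progesterone were higher as a set in DI. Of 19 genes 4 rose and 1 fell adjusted over the list alone, against 0 over all genes. The hedgehog ligand gene Ihh stood at 19.9 ± 9.81 against 5.62 ± 2.19 CPM (1.82 ± 0.47), its receptor Ptch1 had a log2 fold change of 1.52 ± 0.32, the transcription factor Gli1 of 1.93 ± 0.43 and Gata2 of 0.66 ± 0.19, while Acod1 fell. Of these 5 calls 0 held in all 6 fits with a library left out. The set gave adjusted p = 0.0237, and adjusted p = 0.271 with an estimated correlation, a call lost without DI 2 (0.190), PBS 1 (0.166) or PBS 2 (0.0637), and held under 11 of 24 alternatives. Genes that rise with estrogen were lower as a set (median -0.74, adjusted p = 0.00525, and adjusted p = 0.382 with an estimated correlation) with 0 of 25 passing singly in edgeR. DESeq2 called 2 higher and 2 lower over all genes. Members of the list did not go one way: Ramp3 and Igfbp3 had log2 fold changes of 0.84 ± 0.22 and 1.58 ± 0.44, and Sprr2a1 and Lcn2, also in the antimicrobial list, of -1.61 ± 0.53 and -1.85 ± 0.66.

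All 24 cell cycle genes lay above 0 in DI (median 0.69), but 14 of them lay below 0 without DI 1 (median -0.01), and in edgeR 0 passed adjusted over the list alone or over all genes. DESeq2 called 2 higher over all genes, Mcm2 (adjusted p = 0.0179) and Mcm3 (0.0281). The replication helicase genes Mcm2 and Mcm3 had log2 fold changes of 0.64 ± 0.14 and 0.67 ± 0.17, and the set was higher (adjusted p = 3.98e-05, and adjusted p = 0.482 with an estimated correlation). Its level relative to the PBS mean was highest in DI 1 (1.64) and PBS 3 (0.96), and without DI 1 the adjusted p was 0.0790. Without PBS 3 the median was 1.47. Matrix remodelling genes were lower as a set (median -0.79, adjusted p = 7.42e-06, and adjusted p = 0.343 with an estimated correlation), with 1 of 22, the protease inhibitor gene Timp1 (-1.74 ± 0.35), falling adjusted over the list alone and 0 over all genes. That call held in 3 of 6 fits with a library left out, and the list median was -1.47 without DI 2. Immediate early and heat shock genes, which respond to tissue handling, were lower as a set (median -0.54, adjusted p = 0.00231, and adjusted p = 0.431 with an estimated correlation), but not without DI 1 (0.0790), and Hspa1b was at -0.78 ± 0.19. The tight junction list did not pass (adjusted p = 0.200, but 0.00659 without DI 3 and 0.00388 without PBS 3, both lower), and 1 of its members, Cldn7, fell adjusted over the list alone (-0.83 ± 0.17), which held in 1 of 6 fits with a library left out. Clock genes (adjusted p = 0.936, but 0.0199 and lower without DI 3) and transcripts of the mitochondrial genome (0.314) did not pass in the main fit. The mitochondrial list was higher past the threshold under 5 of 24 alternatives (adjusted p 0.00350 to 0.953), which are without PBS 2 (0.0495) and 4 limma settings on FPKM.

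The lists closest to the compound and to the series title had medians nearer 0 than those of inflammation. NRF2, a transcription factor that itaconate derivatives activate, had 26 measured targets with a median of -0.18. Of these 4 fell adjusted over the list alone and 0 over all genes: the heme oxygenase gene Hmox1 (-1.26 ± 0.26), Pgd (-0.48 ± 0.11), Taldo1 (-0.41 ± 0.10) and Osgin1 (-0.70 ± 0.18). Of these calls 0 held in all 6 fits with a library left out, and that of Osgin1 held in 0. In the list of itaconate synthesis and the tricarboxylic acid cycle, 1 of 17 genes fell adjusted over the list alone and 0 over all genes. It was Acod1, which makes itaconate, at 5.96 ± 1.58 against 98.7 ± 88.5 CPM (-4.05 ± 0.86). Without PBS 3 it was at -3.11 and its call was lost (adjusted p over the list alone = 0.0788). Of 26 genes of guanosine and purine nucleoside handling 0 passed singly in edgeR, with Ada at -0.96 ± 0.21, Entpd2 at 0.56 ± 0.14, Hprt at -0.34 ± 0.09 and the nucleoside transporter Slc29a1 at 0.82 ± 0.25. DESeq2 called 2 higher and 3 lower over all genes. As sets, the NRF2, itaconate and guanosine lists were lower at adjusted p = 0.0174, 0.0174 and 0.0158, each with adjusted p = 0.382 with an estimated correlation. The NRF2 call was lost without DI 2 (0.0669) or PBS 2 (0.163), the itaconate call without DI 3 (0.0652) or PBS 2 (0.0630), and the guanosine call without DI 2 (0.0898) or PBS 3 (0.129). They held under 12 of 24, 12 of 24 and 18 of 24 alternatives.

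Annotation terms in the table, which share genes with these lists, asked which gene groups moved over all tested genes. Lower terms included antigen processing and presentation (69 genes, median -0.75, adjusted p = 6.03e-19), phagosome (149 genes, median -0.37, adjusted p = 1.98e-17), the Toll-like receptor signaling pathway (71 genes, median -0.37, adjusted p = 1.32e-10) and adaptive immune response (74 genes, median -0.76, adjusted p = 7.73e-11). Higher terms included the KEGG pathway DNA replication (35 genes, median 0.42, adjusted p = 5.91e-07), the MCM complex (11 genes, median 0.58, adjusted p = 4.08e-05), anterior/posterior pattern specification (43 genes, median 0.29, adjusted p = 9.64e-05) and frizzled binding (14 genes, median 0.29, adjusted p = 0.000748). Of 2649 terms, 260 were lower and 108 higher with a preset correlation, and 0 passed with an estimated correlation, where each term named here had adjusted p = 0.740 with an estimated correlation.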

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

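Tests chosen after the data were seen are those without composition scaling, with counts divided by 4, with a robust fit, with camera on log2 CPM, with DESeq2 lacking a library or with a block, with reduced lists, and of list members lacking a library. Cxcl14 was higher under all 24 alternatives (log2 fold change 0.77 to 1.35, lowest without PBS 3), and its adjusted p ranged from 0.0271 (DESeq2, log2 fold change 1.07, past the threshold) to 0.542. Lower calls for MHC class II genes held under 23 of 24 alternatives, failing with an estimated correlation on log2 CPM, and for proinflammatory mediators, interferon-stimulated genes and macrophage markers under 22 of 24, failing with an estimated correlation on both matrices. The B and plasma cell list held under 16 of 24, the guanosine list under 18 of 24, the eosinophil and mast cell list under 18 of 22, the progesterone list under 11 of 24, the NRF2 and itaconate lists under 12 of 24 and the ovary and oviduct list under 8 of 22. The epithelium list, which did not pass, was lower past the threshold under 8 of 24, and the mitochondrial list higher under 5 of 24. Of 120 calls of members adjusted over their list alone, 44 held in all 6 fits with 1 library left out, and 4 held in 0. DESeq2 called members of further lists over all genes. Lower were 10 other chemokines, 5 bacterial sensing genes, and 9 macrophage, 3 neutrophil, 5 T and NK cell and 4 B and plasma cell markers. Lower too were 6 matrix remodelling, 4 erythrocyte, 3 NRF2 and 1 itaconate list genes. Of other chemokines 1 was higher, and of progesterone genes 3 were higher and 1 lower. With an estimated correlation 1 list was lower and 0 higher, and 0 terms were lower and 0 higher. Camera on log2 CPM called 1 list higher, and 0 lower and 0 higher with an estimated correlation. At a mean FPKM of at least 5, edgeR called 1 lower gene, 746 higher and 858 lower genes had an unadjusted p below 0.05, and 13 lists were lower, with fewer genes tested. Without composition scaling 2390 genes were higher at an unadjusted p below 0.05 and 1 list was higher. Taking an unadjusted p with a log2 fold change of at least 1 gave 436 higher and 778 lower genes, and DESeq2 gave 356 and 767. In limma, 0 genes were lower with no filter, 4 at a mean FPKM of at least 5, 0 with the replicate block, and arrayWeights gave 1 higher and 10 lower. On FPKM 1 list was higher with a pseudocount of 0.1 and 1 with the block. With 1 library left out, edgeR's unadjusted higher genes ranged from 664 to 1667, higher lists from 1 to 3, higher terms from 65 to 167, DESeq2 higher genes from 99 to 699 and lower from 418 to 1045, limma lower genes from 0 to 24 and higher from 0 to 1, with fewer samples. With the replicate block, edgeR gave 0 higher and 0 lower genes (1004 and 1582 at an unadjusted p below 0.05). The block also gave 20 lower and 3 higher lists, and 241 lower and 93 higher terms. The replicate numbers showed no sign of pairing the samples, since deviations from the group mean correlated at -0.05, -0.04 and 0.02. So few samples cannot exclude a pairing, and the labels do not state one.

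Lists that did not pass turned direction under some alternatives. For clock genes the adjusted p was then 0.977 with no filter, 0.885 at a mean FPKM of at least 5, 0.880 with the block, 0.889 with camera on log2 CPM and 0.936 with that and an estimated correlation. On FPKM it was 0.999 with a pseudocount of 1, 0.959 with 0.1, 0.922 with quantile normalization, 0.618 at a mean FPKM of at least 5 and 0.927 with the block. For smooth muscle it was 0.993 with median-ratio scaling of FPKM, 0.517 with quantile normalization and 0.885 with no filter on FPKM. With 1 library left out, in either direction, the adjusted p ranged from 0.0199 to 0.977 for clock genes, which turned without DI 3 (0.0199) and PBS 3, and from 0.0443 to 0.915 for smooth muscle, which turned without DI 1 and PBS 3. It ranged from 0.00240 to 0.900 for stroma, which turned without DI 1, PBS 1 and PBS 2, and from 0.204 to 0.900 for endothelium, which turned without DI 3 and PBS 2. Smooth muscle without PBS 1 (0.0443) and stroma without PBS 3 (0.00240) kept their direction. Other than fewer genes or samples, the cause was not tested. The MHC class II list without H2 genes left fewer than 5 genes and gave no value.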

Other observations

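The tests of the Rps18 and mediator patterns were chosen after their results were seen, while those on intestinal and liver markers and on other splits of the samples were written before. Of the intestinal markers, 1 (Aqp8) was set aside after the result was known, because its group values had been seen earlier, as a member of the estrogen list; this raised the ratio given for PBS 3 and PBS 1.

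Lower Rps18 in DI may reflect how reads were divided between Rps18 and its pseudogenes. Their summed level differed by 0.056 (log2) between the groups, while the other 85 ribosomal protein genes had a median log2 fold change of -0.05. The H2 haplotype that switches H2-Ea, on the same chromosome, was also tested: H2-Ea varied at least 19.5-fold inside each group, and thus did not separate the groups as Rps18 did. Other strain variants were not tested and stay open, both for Rps18 and for the counts of the polymorphic H2 genes, as does an effect of DI.

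The lower median of the proinflammatory mediators in DI does not rest on 1 PBS library alone. With 1 library left out, its highest value was -1.75 (without PBS 3), and 12 of the 19 calls over the list alone held in all 6 fits. Without composition scaling the median was -2.53. TMM factors of 0.946 to 1.07 could not have moved it far, so other faults of scaling stay untested. The result with 1 library left out does not extend to other lists, since the interferon list moved from -1.77 to -0.93 without PBS 3. That is above the bound of -1, which was set for the mediators after their median was known. Fewer leukocytes in DI stay a possible explanation: the mediator score fell by 2.48 and the score of 70 leukocyte markers by 1.23 (log2), a gap between the scores of -1.25. That gap just met the bound set for arguing against fewer leukocytes, and a margin beyond the spread between samples was asked for only after the value was known, so this cannot be told apart from lower expression per cell. An effect of DI, and any difference in infection between the groups, stay open and untested. These are not the only open causes. The estrogen list was also lower and the progesterone list higher as sets with a preset correlation, and hormone state was not tested as a cause.

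Traces of other organs may be present in some libraries. Over 11 intestinal markers not looked at before, the median level was 3.14 CPM in PBS 3, 0.110 CPM in PBS 1 and 0.975 to 1.88 CPM in the other libraries, so PBS 1 stood furthest from the rest; the median ratio of PBS 3 to PBS 1 was 17.9, and 8 of the 11 were highest in PBS 3. Over 13 liver markers not looked at before, the lowest of DI 1, DI 3 and PBS 2 exceeded the highest of the other libraries by a median ratio of 5.49. The most abundant markers reached 137 CPM in PBS 3 (Apoa4, intestine) and 141 CPM in DI 3 (Alb, liver). Neither follows the groups, and whether uterus makes some of these transcripts was not tested.

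The 6 samples can be divided into 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 3105 edgeR genes at an unadjusted p below 0.05 (highest other 2037, so 1 of the 10 splits gave as many), 0 at an adjusted p (highest other 1, 10 of the 10), 1123 DESeq2 genes (highest other 417, 1 of the 10) and 1 limma gene (highest other 1, 2 of the 10). It gave 23 lists (highest other 20, 1 of the 10) and 368 terms (highest other 284, 1 of the 10). The other splits each called 7 to 20 lists with the preset correlation.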
